A study of Mus musculus with 8 samples.

How the data were processed

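Gene expression was measured in 4 liver RNA samples of C57BL/6J mice, each hybridised to 2 arrays. The samples came from wild-type mice and from mice lacking Btg2 (also called TIS21 or PC3), a growth-restraining gene of the BTG/TOB family whose protein binds the CCR4-NOT complex that shortens mRNA tails. Per the labels, the adult livers came from males aged 10 weeks that had been fasted for 20 h. Per the labels' protocols, each fetal sample was a pool of livers from more than 3 littermate fetuses of embryonic day 13.5. The fetal pools were taken as male and female. The series' design text says that every sample was profiled in technical duplicate. The 2 arrays of a group were therefore taken as 2 measurements of 1 RNA sample. All p-values measure array error only: they compare 4 RNA samples, not genotypes, because animals were not replicated. How many adult mice stood behind each adult sample is not given in the sources used here.

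Per the labels' protocols, RNA was extracted with Trizol and 200 ng of each sample was labelled with Cy3 by the Low Input Quick Amp kit. Per the file headers, all 8 arrays lay on 1 slide, were read in 1 scan and were processed with Agilent Feature Extraction 10.7.3.1. The deposited scanner output held the processed signal, the median signal and the local background, each an intensity on a linear scale, with quality flags for every spot. Each array had 59305 non-control spots of 55681 distinct probes. The headers place the first array of every group in row 1 of the slide and the second in row 2. The groups occupied different columns of the slide.

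The deposited value table of the series held linear intensities whose preparation is not given in the sources used here. The median was 18.1 in each of its 8 columns and the 75th percentile was 185 in each, so the arrays had been put on a common scale at least at these 2 quantiles. On the log2 scale its columns correlated with the processed signal of the same arrays at r of 0.995 to 0.999 over the probes. Its scale was thus linear, its genes were not centred and its direction was that of the scanner signal, while the normalization step itself stays unknown. It served as an alternative only.

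Values were computed as log2 of the processed signal minus the 75th percentile of log2 signal on that array. Control spots were left out, and spots carrying an outlier flag (92 to 188 per array) were set to missing. No spot was saturated. Spots of 1 probe were averaged. Probes were named by matching their accessions, without version numbers, to the RefSeq gene table of assembly GRCm38.p6: 26762 probes had a symbol there and 28919 had none. That table was used only for names and for which genes neighbour each other. A probe was tested if it was well above background on both arrays of at least 1 group. A gene with several such probes (3651 genes) was represented by the probe with the highest mean over the 8 arrays. Of 20284 genes with a named probe, 14578 were tested, and 10608 of these were well above background on all 8 arrays. Outlier flags left 3 gene values missing.

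Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), with all 8 arrays in 1 fit of 4 groups, and were adjusted by the method of Benjamini and Hochberg over the genes tested. A call needed an adjusted p under 0.05 and a difference of at least 2-fold. Differences are log2 values with limma's standard error (SE), from 2 arrays per group. Where a gene was not well above background on either array of a group, the brighter group was set against a bound. The bound was the mean, over the dim group's arrays, of the higher of the gene's own signal and the lowest signal among probes well above background. Such differences are given as "at least N-fold". The comparisons were knockout against wild type in the adult samples, the same in the fetal pools, the difference between these effects (an interaction term) and adult against fetal wild type. Overlaps of calls were tested by Fisher's exact test, two-sided, with 4 direction pairs adjusted together.

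Before the data were examined, 49 gene lists were fixed: 30 of pathways or gene families and 19 of cell types. For each list the calls were counted, also with p adjusted over the list alone, and the median log2 difference was placed among the medians of 10000 random lists of the same size matched on mean expression. Because 1 RNA sample stood for each group, the percentile describes these samples. After the data had been seen, 9 further lists were written (intestinal epithelium, heart muscle, fetal lung, epidermis, placenta, body wall mesenchyme, neurons, fasting-induced genes and feeding-induced genes). The genes to be named were chosen by a rule fixed beforehand. In each knockout comparison it took Btg2, the 10 largest rises and 10 largest falls among called genes measured in both groups, and the 5 largest bounds each way. For the adult against fetal comparison and for the interaction it took 5 each way, and for genes called in both knockouts the 10 with the largest smaller difference. From a list it took up to 4 called members with the largest differences and up to 2 members where none was called. Clone and model names were left out of the largest rises, falls and bounds. Genes named outside this rule are said to be so. Some genes that the rule selects are not reported here.

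The procedure was tested on simulated data with the real genes' means and spreads (14578 genes, 50 changed at each fold size). In the simulated adult comparison 86% of 4-fold and 94% of 8-fold changes were called, 0% of 1.5-fold changes and 4 unchanged genes. In the simulated fetal comparison the shares were 94% and 98%, with 2% of 1.5-fold changes and 2 unchanged genes. The small number of arrays limits the precision.

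Alternatives fixed beforehand were another background correction (normexp with an offset of 50), quantile normalization, the 75th percentile of the probes detected on all arrays, median scaling, no filter or a stricter filter on dim probes, outlier spots kept, the mean of a gene's probes, no intensity trend, a fit of only the groups compared, the deposited value table, other fold thresholds, averaged arrays with no test, and each array left out. The files hold no mean foreground signal, so normexp was run on the median signal. Chosen after the data were seen were the slide row as a block, the probes without a symbol kept as features of their own, and the 50 measured genes on each side of Btg2 left out.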

Results

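Liver RNA of wild-type and Btg2-knockout mice was profiled on 8 single-colour arrays, with 2 arrays for each of 4 samples: adult wild type, adult knockout, fetal wild type and fetal knockout. The series names the response to starvation as its subject. All adult mice had been fasted and fed adults were not analysed here, so the comparisons below are between genotypes and between stages. The 75th percentile of signal was 132 to 171 on the adult arrays and 278 to 334 on the fetal arrays. The share of probes well above background ran from 38.5% to 42.3% on the adult arrays and from 48.7% to 61.1% on the fetal arrays. Duplicate arrays correlated at r of 0.992 to 0.997 over the 14578 genes tested. The SD of the difference between duplicates was 0.43 in adult wild type, 0.30 in adult knockout, 0.27 in fetal wild type and 0.24 in fetal knockout, so the adult wild-type pair was the noisiest. Group means of knockout and wild type correlated across genes at 0.982 in the adult samples and 0.991 in the fetal pools, and those of adult and fetal wild type at 0.688; genes are not independent replicates.

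Btg2 was detected in both wild-type samples and in neither knockout sample. Its probe gave processed signals of 149 and 158 on the adult wild-type arrays and of 2071 and 2079.9 on the fetal wild-type arrays. On the 4 knockout arrays it was not well above background, with signals from 4.54 to 8.02. After scaling to the 75th percentile of each array, knockout was at least 7.63-fold lower in the adult comparison (adjusted p = 8.3e-07, limma) and at least 98.0-fold lower in the fetal comparison (adjusted p = 1.4e-06, limma). All 8 arrays matched their labels in this respect. Which part of the gene had been removed, and whether the probe lies in it, is not given in the sources used here. Of the 18 measured members of the BTG/TOB family and the CCR4-NOT complex, Btg2 was the only one called in either knockout comparison (1 of 18 also when adjusted over the list alone). The related Btg1 differed by -0.09 ± 0.05 in adult and -0.07 ± 0.05 in fetal liver, and Tob2 by -0.82 ± 0.04 and 0.25 ± 0.04.

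**Figure D1:**
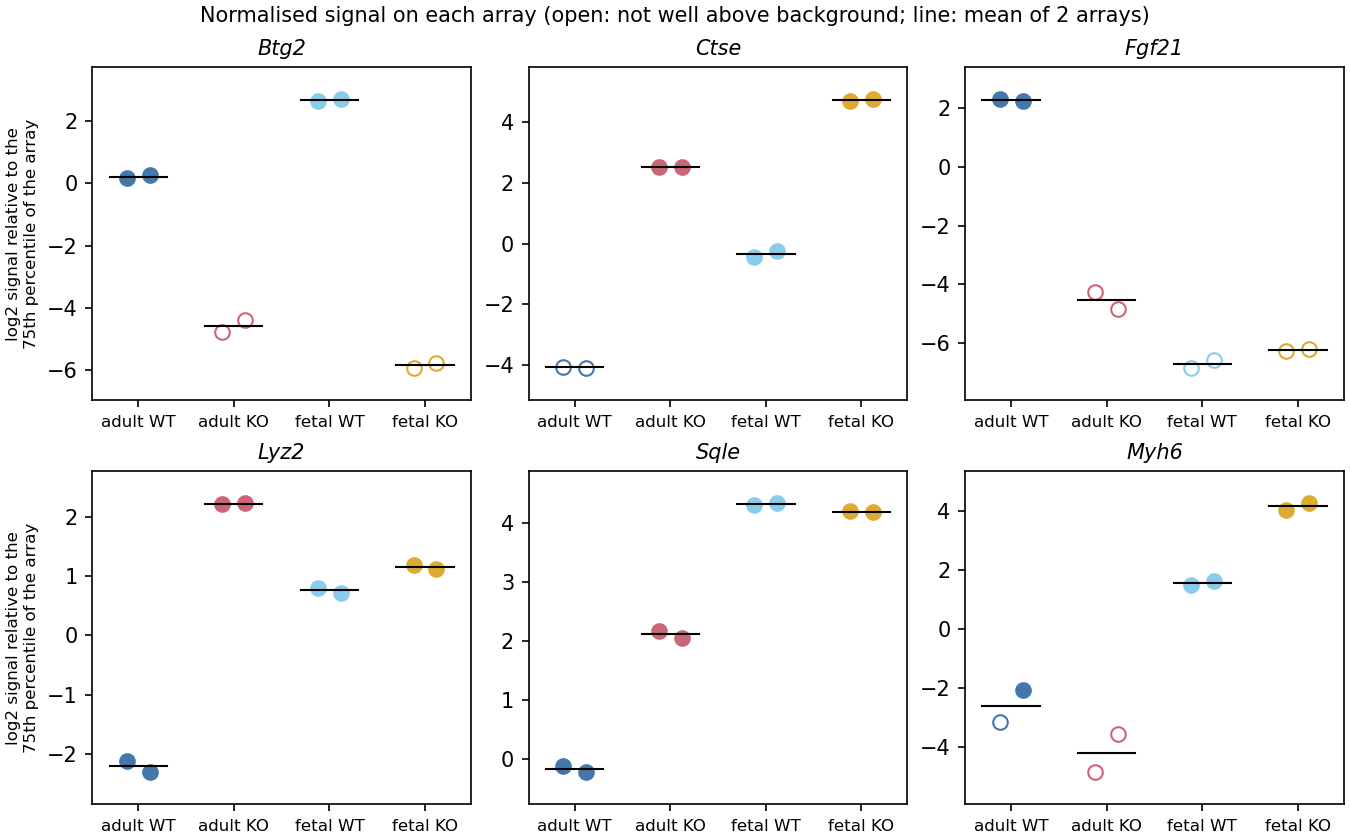
Log2 signal relative to the array's 75th percentile for 6 genes, with a point for each of the 2 arrays of a group, open where the gene was not well above background, and a line at the mean of the pair. Btg2 was dim on all 4 knockout arrays, Ctse was high in both knockout samples, Fgf21 was detected only in adult wild type, Lyz2 and Sqle were higher in adult knockout, and Myh6 was higher in fetal knockout.

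In fasted adult liver, the knockout sample held less RNA of many genes that burn fatty acids, and more RNA of some genes that make cholesterol and of macrophage genes, than the wild-type sample. Of 26 measured fatty acid oxidation genes and targets of PPAR-alpha, the nuclear receptor that switches on fat use in fasting, 14 fell. Of 25 measured cholesterol synthesis genes and targets of SREBP-2, 8 rose. All 14 measured markers of macrophages and Kupffer cells, the resident macrophages of the liver, rose. These counts were the same with p adjusted over the list alone (14, 8 and 14). In all, 1089 of 14578 genes were called, 721 higher and 368 lower in the knockout sample, and 55 of them differed at least 8-fold. Without the first adult wild-type array 778 were higher and 670 lower.

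Among the PPAR-alpha targets, Acot3 fell by 5.08 ± 0.11 on the log2 scale (33.8-fold; adjusted p = 1.1e-07, limma). This gene and Acot2, which fell by 2.71 ± 0.12, encode acyl-CoA thioesterases. Cyp4a14 fell by 3.59 ± 0.09 and Cyp4a31 by 2.44 ± 0.10; both encode fatty acid hydroxylases. The median of the list was -1.01, below all 10000 matched random lists, and all 26 members had negative differences. The median lay between -0.81 and -1.01 under the other scalings and background correction, with 10 to 14 members called. Of 7 ketogenesis genes 2 fell (2 adjusted over the list alone; list median -0.78). These were Acat1, by 1.03 ± 0.03, whose call was lost with normexp and under every other scaling, and Fgf21, which encodes a fasting hormone of the liver. Fgf21 was at least 31.7-fold lower in knockout (adjusted p = 1.6e-06, limma) and was not well above background on either knockout array. The lipid droplet genes Cidec (-3.82 ± 0.13, and -2.47 by another probe) and Cidea (at least 6.05-fold) were also lower. Cidec was the 1 called member of 4 measured adipocyte genes.

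Some fat and sterol synthesis genes were higher. Of 20 lipogenesis genes and targets of SREBP-1c, 6 rose and 2 fell (6 and 2 adjusted over the list alone), and 4 rose and 2 fell with normexp. Thrsp rose by 2.47 ± 0.17, Srebf1, which encodes SREBP-1 itself, by 2.40 ± 0.07, and Scd2, a fatty acid desaturase, by 1.94 ± 0.04. The call of Scd2 was lost with normexp. Mogat1 fell by 1.89 ± 0.59 and its call was lost without any 1 of the 4 adult arrays. The list median was 0.26, at percentile 99.9 of matched random lists. Of the cholesterol genes, Nsdhl rose by 2.51 ± 0.05, Fdps by 2.32 ± 0.03, Sqle by 2.28 ± 0.05 and Cyp51 by 2.18 ± 0.08 (adjusted p = 8.9e-08, 3.4e-08, 1.3e-07 and 9.8e-07, limma). Their list median of 0.80 lay above all random lists. Of 21 bile acid genes, Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 2.17 ± 0.11 and Cyp8b1 by 1.53 ± 0.54, while the transporter gene Slco1a1 rose by 1.69 ± 0.30. The call of Cyp8b1 was lost without any 1 of the adult arrays. That call was also lost under detected-probe scaling, with no filter on dim probes and with the mean of a gene's probes. A fit with no intensity trend and one with unnamed probes kept lost it too. The sign of the bile acid list's median (-0.05) changed with the scaling.

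Macrophage genes gave the highest list median of the 49 fixed lists in this comparison, 2.70, and all 14 members were called under every scaling run and 13 with normexp. Lyz2, which encodes lysozyme, rose by 4.43 ± 0.07 (21.5-fold; adjusted p = 5.4e-08, limma). The scavenger receptor gene Marco rose by 3.64 ± 0.04, Adgre1, which encodes the F4/80 antigen, by 3.23 ± 0.04, and the Kupffer cell gene Timd4 was at least 11.5-fold higher. The complement gene C1qa, also one of the 14, rose by 3.09 ± 0.03. Immune genes outside that list with large rises were Cd300e (3.80 ± 0.11), Cd207 (3.44 ± 0.45), the chemokine gene Cxcl13 (3.32 ± 0.17) and Wfdc17 (3.12 ± 0.04). Of the other blood cell lists, 2 of 13 neutrophil genes rose (S100a8 and S100a9), 1 of 10 T and NK cell genes (Gzma) and 1 of 11 platelet genes (Clec1b). In limma 0 genes were called among 16 erythroid, 6 B cell, 11 stem and progenitor and 6 mast cell genes, with 5, 2, 6 and 2 at an unadjusted p under 0.05. Stellate cell and fibroblast genes had 3 of 16 higher, namely Acta2 (1.71 ± 0.03), Col3a1 (1.66 ± 0.02) and Col1a1 (1.12 ± 0.11), with a list median of 0.55. Among 14 endothelial genes 1 rose (Tek; median 0.37), among 8 mesothelial genes 3 rose, and among 7 cholangiocyte genes 1 rose (Spp1). The 3 called mesothelial genes were not well above background on both arrays of either adult group, and none of the 3 calls held with normexp. With normexp the calls of S100a8, S100a9, Gzma, Tek, Spp1 and Col1a1 were lost too. Those of Col1a1 and Spp1 were also lost without the second adult wild-type array, and that of Spp1 without the first adult knockout array.

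**Figure D2:**
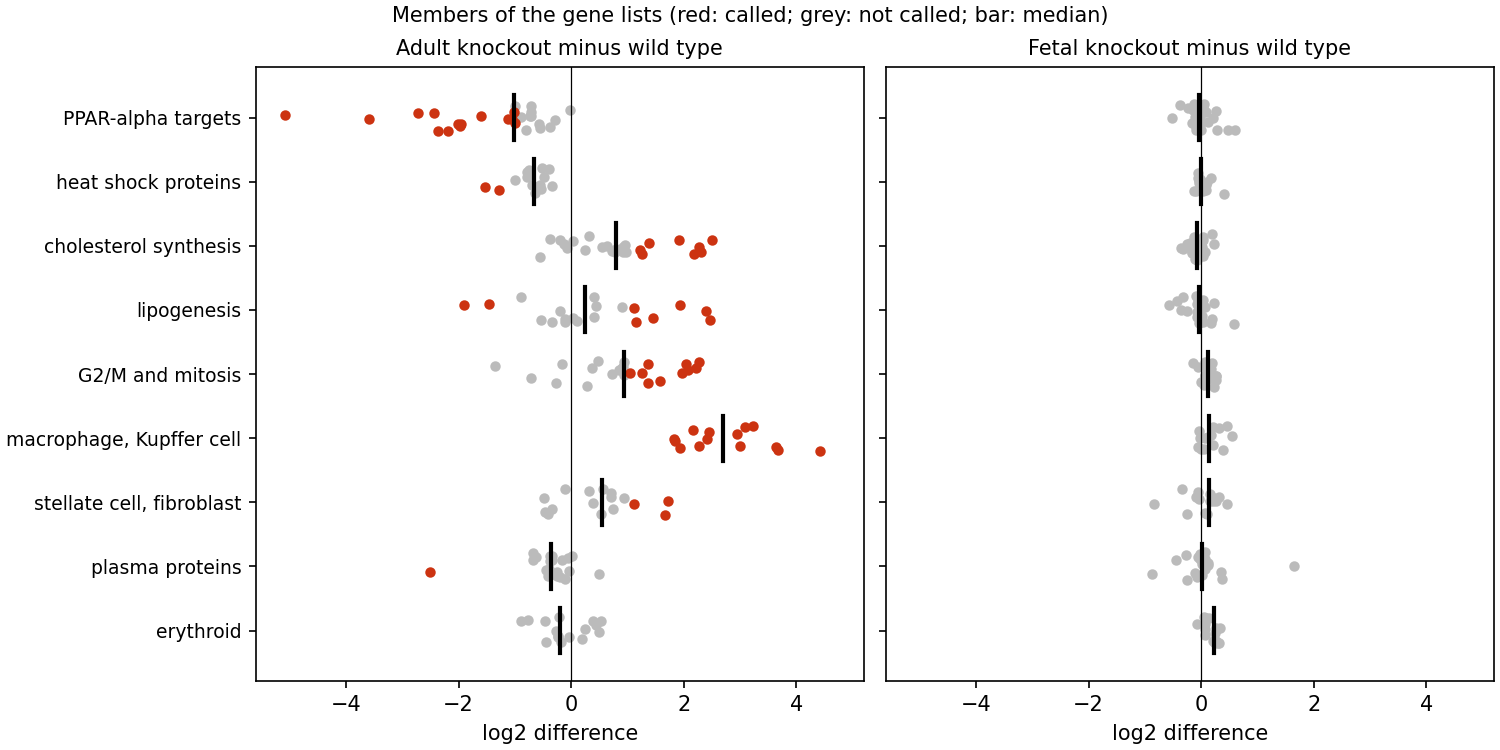
Log2 differences, knockout minus wild type, of the members of 9 gene lists in adult (left) and fetal (right) liver, red where called and grey where not, with a bar at the list median. In the adult comparison PPAR-alpha targets had a median of -1.01 and macrophage genes one of 2.70, while in the fetal comparison the medians were -0.04 and 0.15.

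Some cell cycle genes were called higher in the adult knockout sample, most of the G2/M ones at low signal. Nearly all of the cell cycle calls were lost with normexp, whose offset of 50 shrinks differences of dim signals. Of 23 genes of G2/M and mitosis 10 rose and the list median was 0.94. Cdk1 was at least 1.18-fold and Prc1 at least 2.16-fold higher, both dim in wild type. Mki67 rose by 2.09 ± 0.11, but was well above background on only 1 of the 2 wild-type arrays. Plk1 was also called higher, and no size is given because it was well above background on neither wild-type array and on 1 knockout array. With normexp 0 of the 23 were called in limma and the median was 0.14. The 4 members well above background on all 8 arrays had a median of 1.37. Across the scalings, the value table and normexp the list median ran from 0.14 to 1.40. The members called were then 0 to 15 higher and 0 to 1 lower. Of 23 genes of G1/S and DNA replication 4 rose (list median 0.33), among them Ccnd2 (1.21 ± 0.09) and Ccnd1, which encodes cyclin D1 (1.17 ± 0.02); with normexp Ccnd1 alone was called. For Ccne1 (1.07 ± 0.10) another probe gave -0.42. Of 18 p53 targets 1 rose, Pmaip1 (list median -0.25), which was well above background on 1 of the 4 adult arrays and whose call was lost with normexp.

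All 14 heat shock genes had negative differences, with a median of -0.67 below all matched random lists. The chaperone genes Hspa1a (-1.53 ± 0.18) and Hspb1 (-1.28 ± 0.03) were the 2 called, the former not with normexp. Of 16 glucocorticoid-responsive genes 4 fell, including Gadd45b (-2.90 ± 0.06) and the metallothionein genes Mt2 (-2.58 ± 0.06) and Mt1 (-2.21 ± 0.06), and Lpin1 rose. Of 18 immediate early genes 3 fell, Btg2 itself, Egr1 (-1.66 ± 0.11) and Jun (-1.40 ± 0.03), and Ier5 rose (at least 1.26-fold). The calls of Egr1 and Ier5 were lost with normexp, and that of Ier5 also without the first adult wild-type array. Of 25 genes of the unfolded protein and integrated stress responses 3 rose and 4 fell. Asns, which encodes asparagine synthetase, fell by 2.46 ± 0.04 and the transcription factor gene Atf5 by 1.57 ± 0.02, while Chac1 rose by 1.60 ± 0.07. Of 18 targets of NRF2, the regulator of antioxidant genes, 4 rose and 1 fell, with Gsta1 (2.13 ± 0.12) the largest. The fall, of Srxn1, was lost with normexp and under every other scaling, and the rise of G6pdx with normexp. Of 26 acute-phase genes 3 rose and 2 fell, including Steap4 and Il1r1 (both 1.49) and Lcn2 (-1.63 ± 0.04). Of 19 interferon-stimulated genes 2 rose, with Ifi27l2a at 1.62 ± 0.05, and 3 fell, with Usp18 at -1.07 ± 0.07. The call of Usp18 was lost under normexp and under quantile, median and detected-probe scaling, and under these 4 settings 0 or 1 genes of this list were called lower in limma.

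Of the sex-dependent genes, 5 of 21 male-biased genes rose, Hsd3b5 the most (3.80 ± 0.40), followed by Slco1a1, Nudt7 (1.31 ± 0.03) and C8a (1.18 ± 0.03). Of 17 female-biased genes 3 rose and 4 fell (1 and 3 with normexp), among them Fmo2 (-2.35 ± 0.13) and Ntrk2 (at least 5.45-fold higher, a call lost with normexp). In the growth hormone and IGF axis 2 of 21 genes fell, Socs2 (-2.27 ± 0.08) and Igfbp1 (-1.09 ± 0.05). The call of Igfbp1 was lost with normexp and under every other scaling. Of 22 xenobiotic enzymes 2 rose, Cyp2c55 (3.14 ± 0.26, well above background on only 1 of the 2 wild-type arrays) and Cyp1a2 (1.18 ± 0.11), and 1 fell, Por, whose call was lost under normexp, under every other scaling and without the second adult knockout array. Among 14 glycolysis genes 2 rose, including the hexokinase gene Hk2, well above background on 1 of the 4 adult arrays and not called with normexp. Got1 fell among 19 gluconeogenesis genes (-1.09 ± 0.03), a call lost with normexp and under every other scaling. The urea cycle genes Asl, Oat and Sdsl fell by 1.11 ± 0.03, 1.07 ± 0.03 and 1.05 ± 0.04 among 20 measured, and none of these 3 calls held with normexp or under any other scaling. Of 18 imprinted genes 2 rose and 1 fell; for the latter, Peg3, 2 probes had opposite signs. With normexp 0 of these 3 were called in limma, and Sgce, one of the rises, was also lost with quantile normalization and without the first adult wild-type array. Among 22 plasma protein genes Apoa4 fell by 2.51 ± 0.50 (list median -0.36), among 12 hepatoblast genes Gpc3 fell, among 13 mature hepatocyte genes Cyp1a2 rose, and among 19 globin and haem genes Hbb-bh1 rose. With normexp the calls of Gpc3 and Hbb-bh1 were lost, and that of Hbb-bh1 also with quantile normalization and without any 1 of 3 adult arrays. In limma 0 genes were called of 17 circadian, 26 oxidative phosphorylation, 24 ribosomal protein, 4 sex-linked, 8 skeletal muscle, and 6 kidney and adrenal genes, with 10, 25, 19, 0, 2 and 3 at an unadjusted p under 0.05.

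Of 10 pancreas and gut markers 2 rose in the adult knockout sample, Reg1 (at least 4.31-fold) and Vil1 (at least 1.06-fold), and 2 fell, Fabp2 (-1.39 ± 0.03) and Lgals4 (-1.31 ± 0.05). The calls of Reg1 and Vil1 were lost with normexp. The median of that list was -0.22. In a list of intestinal epithelium genes chosen after the data were seen, 10 of 17 rose and 2 fell, with a median of 2.31. Its 4 members that were well above background on all 8 arrays had a median of -0.65. That filter leaves out members dim in any sample, so it cannot test a rise from background. With normexp 1 member rose and 2 fell. Of 3 lung markers 1 was called higher, Sftpa1, and 0 in limma when adjusted over the list alone, with 1 at an unadjusted p under 0.05. The call of Sftpa1 was lost with normexp and without any 1 of the adult arrays. Single genes with large bounds were Ren2, of the renin family (at least 34.3-fold higher), Ctse, which encodes cathepsin E (at least 32.3-fold), Prap1 (at least 17.8-fold) and Adamdec1 (at least 10.65-fold). Ren2 and its neighbour Ren1 are near-identical in sequence, and C57BL/6 mice are usually taken to carry Ren1 alone. What the Ren2 probe measured here is therefore uncertain. Hsd17b6 rose by 3.30 ± 0.15. Further large falls were those of the monocarboxylate transporter gene Slc16a5 (-4.03 ± 0.26, and -1.15 by another probe), Kiss1, which encodes kisspeptin (-4.01 ± 0.23), the oestrogen sulfotransferase gene Sult1e1 (-3.18 ± 0.37), Lamb3 (-3.15 ± 0.18), Myom3 (-2.87 ± 0.15) and Cgref1 (-2.73 ± 0.03). Cntnap1 was at least 7.57-fold and Nipal1 at least 7.36-fold lower.

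Of the other lists written after the data were seen, 17 fasting-induced genes outside the PPAR-alpha list had a median of -0.18, with 1 higher (Lpin1) and 1 lower (Igfbp1), and the sign of that median changed with the scaling. Of 15 feeding-induced genes 5 rose, among them Thrsp, Srebf1, Scd1 and Fasn, with a median of 0.45 (5 also adjusted over the list alone). All of these named genes also belong to the lipogenesis list, so their rises are not a separate result. The call of Fasn was lost with normexp. In the adult comparison 2 of 19 heart, 1 of 7 fetal lung, 3 of 15 epidermis, 1 of 18 body wall and 1 of 10 neuron genes were called, and 0 of 6 placenta genes in limma, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, these counts were 1, 0, 3, 0, 1 and 0, and with normexp 0 members of these 6 lists were called in limma.

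In the adult comparison 21 of the 49 fixed lists had a median outside the central 95% of matched random lists, 12 above and 9 below. Lists of independent genes would give 2.45, but members of a list can vary together and some lists share members. The count is therefore not a test of genotype. With p adjusted over the list alone, the counts of the fixed lists equalled those over all genes, except for lung. The number of genes changed in adult knockout was 1256 at a 2-fold difference of averaged arrays with no test, and 347 with normexp. Calls were 66.2% higher ones, 53.7% without the first adult wild-type array and 78.1% under detected-probe scaling, where the median of all genes moved from -0.10 to 0.03.

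In fetal liver, 281 genes were called, 73 higher and 208 lower in the knockout pool. The split was 28 and 39 with normexp, 131 and 250 with no filter on dim probes, and 41 and 152 without the second knockout array. Heart genes were among the higher ones. Myh6, which encodes cardiac myosin, rose by 2.60 ± 0.46 (6.06-fold; adjusted p = 0.0082, limma), the atrial light chain gene Myl7 by 2.44 ± 0.16, the atrial peptide gene Nppa by 2.15 ± 0.11 and the heart and limb regulator Tbx5 by 1.94 ± 0.30. Skin genes were among the lower ones, with falls of the keratin genes Krt15 (-2.34 ± 0.20), Krt14 (-2.30 ± 0.23) and Krt5 (-2.28 ± 0.32), of Krtdap (-2.74 ± 0.22) and of the plakophilin gene Pkp1 (-2.52 ± 0.19). The p53 target Phlda3 rose by 2.16 ± 0.06 and Hamp, the gene of the iron hormone hepcidin, by 1.91 ± 0.06.

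Of the 10 largest rises the others were Ctse (5.05 ± 0.07; adjusted p = 4.7e-07, limma), the surfactant gene Sftpc (2.42 ± 0.31), Cst9 (2.29 ± 0.22) and Tbx4, a regulator of lung and hindlimb (2.10 ± 0.21). Mybphl was at least 6.89-fold, Foxf2 at least 2.56-fold, Otos at least 2.28-fold and Peg3os at least 2.07-fold higher, all dim in the wild-type pool. Cxcl14, a chemokine gene, fell by 3.38 ± 0.09 (adjusted p = 8.7e-06, limma). The homeobox genes Six2 and Msx1 fell by 3.37 ± 0.23 and 2.29 ± 0.17, the enkephalin gene Penk by 2.23 ± 0.12 and Prl8a2, a prolactin relative made by the placenta and uterus, by 1.98 ± 0.23. Trim29 was at least 6.53-fold, Bcl11b at least 6.04-fold, Tff1 at least 5.88-fold and Gjb6 at least 5.32-fold lower. The calls of Foxf2, Otos, Peg3os, Prl8a2 and Trim29 were lost with normexp, and those of Foxf2, Otos, Peg3os and Myh6 without the second knockout array. The call of Foxf2 was also lost without the first knockout array and that of Peg3os without the first wild-type array.

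Lists of genes of neighbouring fetal tissues, written after the data were seen, differed as well. Of 19 heart muscle genes 10 rose, all 19 had positive differences and the median was 1.25. Of 15 epidermis genes 11 fell (median -2.31), of 18 body wall, skeletal and limb genes 15 fell (median -2.27), of 6 placenta genes 4 fell (median -1.83) and of 10 neuron genes 7 fell (median -1.13). Of 7 fetal lung genes 2 rose (median 0.29). Some members had been seen before the lists were written. Without them the medians were 0.99 over 15 heart genes, -2.31 over 11 epidermis genes, -1.99 over 14 body wall genes, -0.91 over 4 placenta genes and 0.20 over 5 lung genes. With normexp the heart median was 0.99, the epidermis median -0.88, the body wall median -0.67, the placenta median -0.36 and the neuron median -0.37. The calls in these lists were then 9 heart genes higher and 6 epidermis, 6 body wall, 0 placenta and 1 neuron genes lower in limma. Among the 3 lung genes fixed beforehand Sftpc rose and Sftpd fell, as also when adjusted over the list alone. Sftpd was not well above background on either knockout array and its call was lost with normexp.

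Genes of liver cells differed little. In limma 0 of 12 hepatoblast genes were called (median -0.03), with 4 at an unadjusted p under 0.05, and 1 of 13 mature hepatocyte genes, Pck1, which was lower. Pck1 was not well above background on either knockout array, and its call was lost with normexp, with quantile normalization and without the first wild-type array. Genes of erythroid cells, the most numerous cells of the fetal liver, had a median of 0.22 and 15 of 16 positive differences, at percentile 99.99, with 0 called in limma and 6 at an unadjusted p under 0.05. The 19 globin and haem genes had a median of 0.22 with Hbb-bh1 called higher, a call lost without any 1 of the fetal arrays, and the 13 neutrophil genes one of 0.31 with 0 called in limma and 5 at an unadjusted p under 0.05. Urea cycle genes had a median of -0.10, below all matched random lists, with 0 of 20 called in limma and 14 at an unadjusted p under 0.05. PPAR-alpha targets, cholesterol genes and macrophage genes, which moved in the adult comparison, had medians of -0.04, -0.08 and 0.15, with 0 called in limma and 13, 12 and 8 at an unadjusted p under 0.05. Among matched random lists the PPAR-alpha and cholesterol medians lay at percentiles 0.31 and 0.08. The sign of the PPAR-alpha median changed under median scaling. No fixed list had more than 2 calls, and 17 of 49 medians lay outside the central 95% of matched random lists, 10 above and 7 below. With p adjusted over the list alone the counts of the fixed lists were the same. Of the 281 calls, 108 concerned genes well above background on both arrays of both fetal groups. Restricted to genes well above background on all 8 arrays, 26 genes were called, and with normexp 67.

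The knockout minus wild-type difference was called different between the stages for 1419 of 14578 genes by the interaction term. Of these, 877 had a more positive difference in adult liver and 542 a more negative one. The split was 1178 and 342 under detected-probe scaling, 938 and 313 under median scaling, 255 and 216 with normexp, and 1152 and 1202 with unnamed probes kept. By the naming rule the genes with a more positive difference in adult liver were Ren2, Prap1, Clec2h, Guca2b and Adamdec1, and those with a more negative one included Fgf21, Acot3 (-4.98 ± 0.15), Slc16a5 and Cidea. Of these 9 genes Acot3 alone was well above background on all 8 arrays, so no sizes are given for the others. By lists, the interaction was called for all 14 macrophage genes (median 2.60), for 13 of 25 cholesterol genes (median 1.02), for 11 of 26 PPAR-alpha targets (median -0.90) and for 10 of 23 G2/M genes (median 0.89), with the same counts adjusted over the list alone. Btg2 itself was called too, but no size is given, since it was not well above background on any knockout array. Most of the adult calls of the G2/M genes were at low signal, and with normexp 0 of the 23 were called in limma in the adult comparison. The 4 members well above background on all 8 arrays had an adult median of 1.37. Stage was not separated from fasting, sex and cell make-up. Each group was 1 RNA sample, so genotype was not separated from other differences between single samples, such as their tissue make-up.

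**Figure D3:**
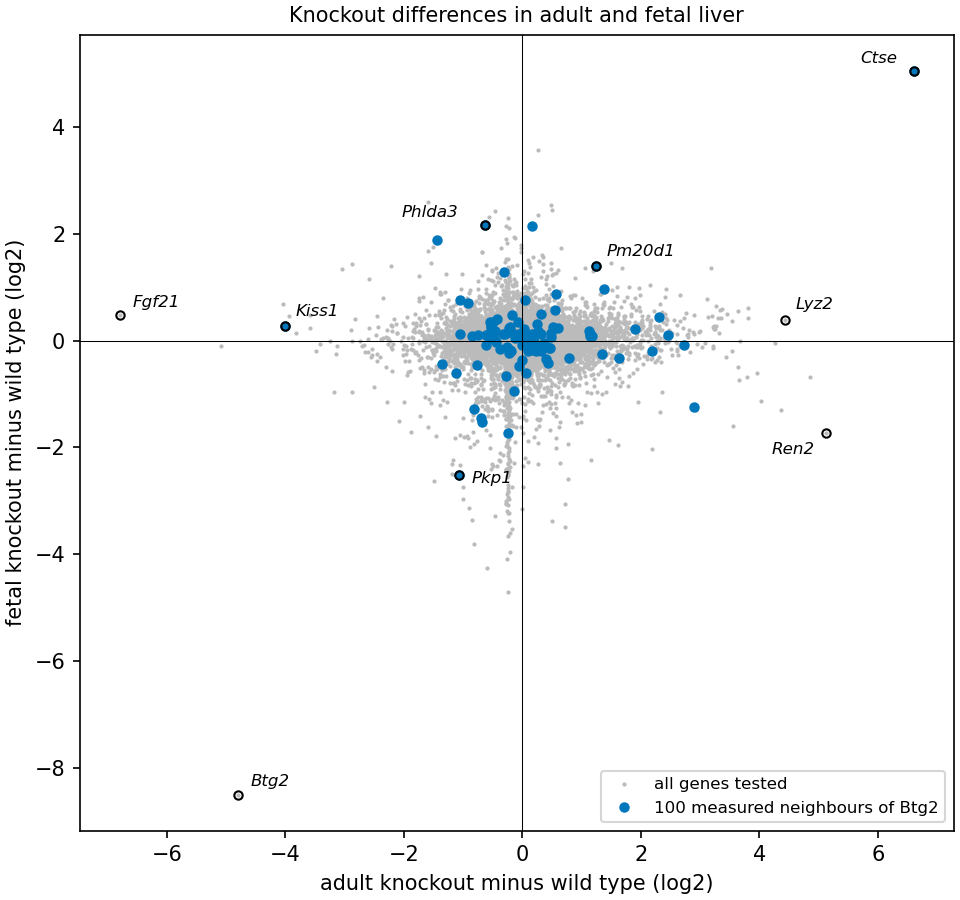
Knockout minus wild type, log2, in adult liver (horizontal) against fetal liver (vertical) for the 14578 genes tested (grey), with the 100 measured neighbours of Btg2 in blue and 9 genes named. Btg2 was low and Ctse high on both axes, Fgf21 and Lyz2 moved on the adult axis, and Phlda3 on the fetal axis.

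Between the wild-type samples, adult liver differed from fetal liver in 8020 of 14578 genes, 3985 higher and 4035 lower in the adult. The adult mice were fasted males and the fetal pools were taken as male and female, so stage was not separated from fasting and sex. Adult liver held more RNA of many genes of mature liver function. Cyp2e1 was higher by 13.90 ± 0.03, Cyp4a31 by 13.14 ± 0.10, Pck1, the gene of the key gluconeogenesis enzyme, by 13.04 ± 0.17, Cyp4a10 by 12.95 ± 0.24 and Cyp2a4 by 12.13 ± 0.14. Other probes gave 10.22 for Cyp4a31 and 15.95 for Cyp4a10. Serpina3k was at least 44251-fold higher, and Cyp4a14, Mup20, Mug1 and Mup4 were likewise not well above background in fetal wild type. All 13 mature hepatocyte genes (median 10.73, but 8.08 over the 9 well above background on all 8 arrays and 8.19 with normexp), all 26 PPAR-alpha targets (median 4.13), all 20 urea cycle genes (median 5.50), all 22 plasma protein genes (median 3.58) and 16 of 17 circadian genes (median 3.33) were higher in the adult. Fetal liver held the genes of blood formation and growth. Afp, the fetal serum protein gene, was lower in the adult by -10.58 ± 0.03, the red cell anion exchanger gene Slc4a1 by -9.46 ± 0.08, Cd24a by -8.69 ± 0.10 and Unc93a2 by -7.94 ± 0.08. For the imprinted gene Plagl1 (-8.22 ± 0.07) another probe gave 0.20. The embryonic globin genes Hbb-y and Hbb-bh1 were at least 4344-fold and at least 808-fold lower in the adult, Dlk1 at least 2066-fold, the blood group gene Rhd at least 713-fold and Cstdc5 at least 615-fold. Of 16 erythroid genes 14 were lower, of 23 G2/M genes 22, of 23 G1/S genes 22, of 13 neutrophil genes 11 and of 18 imprinted genes 16. Btg2 was lower in the adult by -2.45 ± 0.16, while Tob1 was higher by 3.80 ± 0.07. Xist, the RNA of the inactive X chromosome, was well above background on both fetal wild-type arrays and on neither adult one. Counts adjusted over the list alone were the same for these lists. The share of higher genes, 49.7%, fell by scaling to 30.4% with the median, where the median of all genes moved from -0.01 to -0.63.

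Few genes were called in both knockout comparisons. There were 18 in the same direction and 16 in opposite directions. Of the former, 6 were higher in both (3.61 expected of independent lists, Fisher's exact test p = 0.18, adjusted 0.24). The other 12 were lower in both (5.25 expected, Fisher's exact test p = 0.0067, adjusted 0.027). These 12 include Btg2, the knocked-out gene itself, and its neighbour Pkp1, so this test does not speak for other genes alone. Of the 16 in opposite directions, 12 rose in adult and fell in fetal liver (10.3 expected, Fisher's exact test p = 0.52). The remaining 4 did the reverse (1.84 expected, Fisher's exact test p = 0.11). Across genes the differences of the stages correlated at r = 0.01 and rho = -0.10, and genes are not independent replicates. By the naming rule the shared genes were Btg2, Ctse (5.05 ± 0.07 in fetal liver), Mpped1 and Hoxa6, which were lower in both but dim in both adult groups, and 6 genes with opposite directions. Ren2 was higher in adult and lower in fetal knockout (-1.74 ± 0.15), as were Guca2b (-1.60 ± 0.22 in fetal liver), Klk1b3 (1.46 ± 0.17 in adult liver) and the model gene Gm4956 (1.62 ± 0.12 in adult liver), both dim in the fetal knockout pool. With normexp both calls of Mpped1, Hoxa6 and Klk1b3 and the fetal call of Gm4956 were lost. The muscle gene Csrp3 (-1.54 ± 0.03 and 1.45 ± 0.03) was lower in adult and higher in fetal knockout. Myh6 was called likewise, but it was well above background on 1 of the 4 adult arrays and its adult call was lost under 4 alternatives, so no adult size is given. Without the first adult wild-type array the counts were 39 and 25.

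Genes near Btg2 on its chromosome were called more often than genes elsewhere. Among the 50 measured genes on each side, by gene order in GRCm38.p6, 20 of 100 were called in the adult comparison, against 7.38% of the other 14477 genes (Fisher's exact test, odds ratio 3.14, p = 4.1e-05). In the fetal comparison 10 of 100 were called, against 1.87% (Fisher's exact test, odds ratio 5.84, p = 2.2e-05). Of the adult calls 15 were higher, against 706 of the other genes (Fisher's exact test p = 0.00011). The 5 lower ones, against 362, were not a clear excess (Fisher's exact test p = 0.11). Of the fetal calls 5 were higher, against 68 (Fisher's exact test p = 0.00014), and 5 lower, against 202 (p = 0.014). With quantile normalization or the deposited value table, only 2 neighbours were lower in fetal knockout (Fisher's exact test p = 0.31 for each). The excess of fetal falls held with normexp and under median and detected-probe scaling (Fisher's exact test p = 0.028, 0.013 and 0.018). Ctse, Pm20d1 and Pkp1 were called in the same direction at both stages, and Lct and Chil1 in opposite directions. With normexp 8 of the 100 were called in the adult comparison, against 338 of the other genes (Fisher's exact test p = 0.0026). In the fetal comparison 7 were then called, against 59 (Fisher's exact test p = 3.2e-07). Among the calls lost with normexp were the adult ones of Pkp1, Lct, Chil1 and Ren1 and the fetal ones of Lct, Elf3, Inava and Fcmr. The adult call of Pkp1 was also lost under median and detected-probe scaling. Kiss1 (-4.01 ± 0.23 in adult liver), Ren1 (1.34 ± 0.17 in adult liver) and Phlda3 lie there too. Pm20d1 and Ren1, and this comparison as a whole, were chosen after the values had been seen.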

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

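All tests of explanations in this part were chosen only after the results had been seen.

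Genes near Btg2 were called more often than genes elsewhere in both knockout comparisons. Clustering of related genes, of the kind other windows of neighbouring genes show, could not be decided by counting calls in windows. The neighbours of Btg2 were tested because their calls had been seen, and their fetal count passed the highest other window only narrowly. With quantile normalization 7 neighbours were called in the fetal comparison, and other windows were not counted under that setting. In the fetal comparison 0 of 12466 other windows held as many calls as the 10 near Btg2 (highest 9), and in the adult comparison 6 held as many as the 20 near Btg2 (highest 21). DNA of another strain left around the knocked-out locus could give such calls. The share of 0% is what this explanation predicted, without showing that it holds. That prediction was written after the excess had been seen and restates it. A cluster of related genes, of the general kind or particular to this place, stays open. The 5 falls among the 10 fetal calls (Pkp1, Elf3, Inava, Lct and Myog) may belong to the tissue pattern of the next paragraph. Among the adult rises, Ptprc, a white blood cell gene (2.73 ± 0.13), and the lactase gene Lct (2.89 ± 0.32) may likewise belong to the macrophage and intestinal patterns. Both were named after the values had been seen, and the other adult rises were not sorted in this way. Genotypes at the neighbours and the strain of the cells in which the gene was removed were not tested. Effects of the deletion on nearby genes were not tested either.

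Heart genes were higher and skin and body wall genes lower in the fetal knockout pool. The heart list had a median of 1.25, and all 19 members, each well above background on the 4 fetal arrays, were higher in the knockout pool, so heart tissue taken with the knockout livers may account for them. The epidermis list had a median of -2.31, so skin and body wall tissue taken with the wild-type livers may account for these. A lower share of liver cells in either pool as the only cause would move heart and epidermis genes alike. It was argued against for these genes. Over the 15 and 11 members not seen before the lists were written, their medians differed by 3.30 (bootstrap 95% interval 1.63 to 3.92). The lists followed from members already seen to move oppositely, and genes of a tissue can move together, so this was not an independent test. The interval draws genes of 1 pool per genotype. A change of these genes within liver cells stays open, as do fetuses of slightly different age, since each genotype was 1 pool.

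PPAR-alpha targets were lower in the adult knockout sample. Less hepatocyte RNA as the only cause was argued against, because their median lay below that of plasma protein genes by -0.65 (bootstrap 95% interval -1.59 to -0.38). That interval draws genes of 1 RNA sample per group. The plasma protein genes themselves had a median of -0.36 and 20 of 22 negative differences. That median lay at percentile 9.6 of matched random lists, and oxidative phosphorylation genes had one of -0.39 with 24 of 26 negative. The plasma protein median is therefore no sign particular to less hepatocyte RNA, whose part stays open. Array scaling was argued against, as at least 10 targets were called lower under each of 3 other scalings, against 14. A weaker or later fast in the knockout mice could not be decided: fasting-induced genes outside the list had a median of -0.18 and feeding-induced genes one of 0.45. The feeding-induced list was written after the data were seen and shares genes with the lipogenesis list. An effect of Btg2 on fat use likewise stays open, as animals were not replicated.

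The knockout minus wild-type difference was called different between the stages for 1419 genes, with 1 RNA sample per group. Large interaction values were 6.86 for Ren2, 5.67 for Prap1, 5.54 for Clec2h, 5.15 for Guca2b, 5.15 for Adamdec1, -7.27 for Fgf21, -4.98 for Acot3, -4.72 for Slc16a5 (-1.39 by another probe) and -4.40 for Cidea. Acot3 alone of these was well above background on all 8 arrays, so the other values are not sizes of a change. Probes without a gene symbol, left out of the comparisons by gene, also differed: of 9918 tested, 630 were called in the adult comparison (253 higher and 377 lower) and 140 in the fetal comparison (75 higher and 65 lower).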

How the results depend on the processing

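The slide row as a block, the probes without a symbol and the omission of the neighbours of Btg2 were chosen only after the results had been seen. No paired analysis was possible because the labels give no replicate numbers. The slide row, a position and not a pairing of samples, gave as a block 1087 genes changed in adult knockout and 275 genes changed in fetal knockout. The planned block for slide or scan was not run because all arrays lay on 1 slide and were read in 1 scan.

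In the Btg2 knockout check, the falls in adult and fetal liver kept their direction and call under every alternative that tested the gene. They are not sizes, as the knockout arrays were dim. With normexp background correction, whose offset of 50 shrinks differences of dim signals, they were -1.78 and, in the Btg2 knockout check, fetal, -4.62. Without each array, 12 to 14 PPAR-alpha targets were called lower, 8 to 9 cholesterol genes higher and 14 macrophage genes higher in adult knockout.

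The count of genes changed in adult knockout was 1089, and 347 with normexp background correction, of which 334 were among the 1089. It was 501 among genes well above background on all 8 arrays and 1704 with unnamed probes kept, where fewer or more features were tested. It was 8106 with no fold threshold, 2664 at 1.5-fold or more and 1064 to 1448 without each array. The number of genes changed in fetal knockout, 281, was 67 with normexp, 26 well above background on all 8 arrays, 3281 with no fold threshold, 483 at 1.5-fold and 193 to 303 without each array. The number of genes for which the knockout effect differs by stage, 1419, was 471, 693, 7573 and 3388 in the same order, 2354 with unnamed probes and 1314 to 1735 without each array. The number of genes differing between adult and fetal wild type, 8020, was 5331 well above background on all 8 arrays, 12999 with unnamed probes, 12683 with no fold threshold and 7899 to 8134 without each array. By construction the normexp offset of 50 shrinks differences of dim signals, so a call lost with normexp does not by itself show that a gene did not differ. How many of the lost calls the offset accounts for was not tested.

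The genes changed in both knockouts in 1 direction numbered 18. They were 3 with normexp, 5 well above background on all 8 arrays, 29 with unnamed probes, 720 with no fold threshold, 56 at 1.5-fold, 34 with averaged arrays and no test, and 14 without Btg2 and its neighbours. Without each array they were 12 to 39, the highest without the first adult wild-type array. The 16 genes changed oppositely in the knockouts were 4 with normexp, 27 with median scaling, 3 well above background on all 8 arrays, 1670 with no fold threshold, 59 at 1.5-fold, 27 with averaged arrays, and 14 to 25 without each array, the highest again without the first adult wild-type array. The cause was not tested. The G2/M genes called higher in adult knockout, 10, were 0 with normexp and 3 well above background on all 8 arrays.

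Medians of 49 fixed lists changed sign under another scaling, the value table or normexp in 18 lists for adult knockout, 20 for fetal knockout and 6 for wild type. Igll1 in adult against fetal wild type was 0.083 with normexp, and the fetal PPAR-alpha median was 0.0011 with median scaling. The fetal female-biased median was -0.016 without the first fetal wild-type array and otherwise up to 0.25 without an array. The fetal lung cell median was -0.05 without the second fetal wild-type array and -0.061 without the first fetal knockout array, and otherwise up to 1.09 without an array. The cause was not tested. Among members well above background on all 8 arrays, which are fewer, the medians of several lists reversed, and only examples are given. They became -0.088 for fetal female-biased genes, -0.014 for adult xenobiotic enzymes, 0.76 for adult adipocyte genes and -0.65 for adult intestinal genes. The filter leaves out members dim in any sample, so for the intestinal genes it cannot test a rise from background. Adult erythroid genes went from -0.20 to 0.20. In adult against fetal wild type the medians became 0.68 for mesothelium and 0.32 for epidermis, and p53 targets went from -0.37 to 0.43.

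With median scaling the second array of adult wild type lay -0.47 from the first by the median gene and that of fetal wild type 0.42, against -0.02 and -0.0006 with the 75th percentile. limma's prior degrees of freedom were then infinite, so genes of equal intensity shared 1 variance and the p-values of this scaling were not comparable with the others. Of 923 called values of genes taken by the naming rule, list members and neighbours of Btg2, normexp lost 247 and turned the sign of 29, the other scalings and the value table lost 57 to 73 and the slide row block 2. Signal over background limits the fold of dim genes: 140 adult and 18 fetal calls were dim in both groups compared.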
